A study of Mus musculus
Rattus norvegicus and Mus musculus and Rattus norvegicus with 95 samples.

How the data were processed

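RNA sequencing covered 8 bulk libraries of mouse ESCs, rat ESCs and mouse-rat allodiploid ESCs (AdESCs), each from 1 cell line, and 87 single cells of AdESCs and their derivatives captured on a microfluidic C1 chip. The labels describe the bulk samples as G0/G1 cells. They give Trizol for RNA extraction, a TruSeq kit for libraries and a HiSeq 2000 for sequencing. Fibroblasts came from a mouse chimaera of line MR1-1, neurons and somatic testis cells from a mouse chimaera of RM1-1, lung and somatic testis cells from a rat chimaera of RM2-1, and embryoid bodies (EBs) from MR2-1 and RM1-1. The replicates are separate lines, and no label says whether libraries came from separate cultures or days, so p-values measure only the spread between these samples.

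The deposited values are FPKM made by the authors, 1 value per gene and library. The unit is not written in the tables; it was taken from the submitters' processing notes, which name FastQC 0.10.1, TopHat2 2.0.10 and Cufflinks 2.1.1 with the builds mm10 and rn5, and checked against the size of the values. Both tables hold the same 13926 homologues, identified by a homologue number and a mouse symbol. How mouse and rat values of a gene were joined in AdESC libraries is not stated, and an AdESC value cannot be split here into a mouse part and a rat part. A sum, a mean or a joint reference would give other AdESC values, so the differences between AdESCs and either parent, the calls against the parental mean and the classes by parent depend on that step. A gene listed at 0 in a species is given no fold, since the tables do not part a missing gene model from missing transcripts, nor do they at values near 0. In both rat lines alone 1273 genes were listed at 0, of which 94 had a mouse mean of 10 FPKM or more. In both mouse lines alone 352 were, of which 7 had such a rat mean. Over the 94 genes the AdESC mean was 0.47 of the mouse mean in the median (quartiles 0.29 and 0.58).

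Read depth is unknown because the values are FPKM, so no counting interval or detection floor is given. The spacing of low values gave ratios of depth between bulk libraries from 0.62 to 1.424, read from 6.993% to 26.298% of the low genes. The precision of single cells was described by the median over genes of the SD of log2(FPKM + 1) between the cells of a sample. It ran from 1.155 (RM1-1 AdESC) to 1.434 (MR2-1 AdESC) in AdESC samples and from 1.406 (RM2-1 testis) to 1.791 (MR1-1 fibroblast) in differentiated ones. Cells per sample were 6 (MR1-1), 8 (MR2-1), 4 (RM1-1) and 6 (RM2-1) for AdESCs. They were 12 (MR2-1) and 5 (RM1-1) for EBs, 4 (RM1-1) and 20 (RM2-1) for testis, 10 for fibroblasts, 8 for neurons and 4 for lung. Cells are not replicates, so each sample entered the tests as the mean FPKM of its cells.

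Chromosomes came from a RefSeq gene table of GRCm38.p6 by gene name: 13295 genes matched by symbol, 597 by an older symbol and 34 not at all, giving 445 X-linked and 13447 autosomal genes. Coordinates were not used. Differences between groups were fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend in the prior variance, for genes with a mean of at least 1 FPKM over the samples of the fit (8794 bulk, 8421 single-cell). P-values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. The bulk fits had mouse ESC, rat ESC and AdESC as groups, with RM and MR apart for the comparison between them, and the AdESC group was also tested against the mean of the parental groups on the log2 scale. The single-cell fits set 7 differentiated samples against 4 AdESC samples, and EB and testis samples (2 each) against AdESCs and against each other. Genes were classed by their calls against each parent, with chance shares from 50 simulations of unchanged groups and from independent lists.

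Lists of genes were fixed before the data were examined, 39 in all, of which 14 hold markers of cell types. Those of pathways and states were naive pluripotency, primed epiblast, mesoderm and endoderm, neuroectoderm, trophoblast, the 2-cell-like state, paternally and maternally expressed imprinted genes, DNA methylation, polycomb and chromatin, Wnt, MAPK and p53 targets, interferon response, unfolded protein response, glycolysis, nuclear and mitochondrial respiratory genes, ribosomal proteins, G1/S, G2/M, cholesterol synthesis, germ cell, X escape and X-linked genes. Those of cell types were fibroblast, feeder fibroblast, stroma, myoid, neuron, glial, lung epithelial, endothelial, leukocyte, erythroid, Sertoli, Leydig, visceral endoderm and cardiac muscle. Each was tested by camera with a preset correlation of 0.01 and with an estimated one, adjusted over the lists, when at least 3 members passed the filter. The mitochondrially encoded list had 0 of 15 members measured and the 2-cell-like list 1 of 18, and the erythroid list had 4 of 12, too few past the filter, so none of these was tested.

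Named genes followed a rule set with the lists. They are the 10 largest changes in each direction among called genes whose groups do not overlap, up to 4 members of each list discussed (the largest changes among called members, otherwise the highest means), and Pou5f1, Sox2, Nanog and H19. Predicted genes were passed over. For samples without a replicate the rule took the 10 largest changes among genes at a mean of 10 FPKM or more, and their lists were ranked against 10000 random lists matched on level. Xist was not analysed here.

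For X-linked transcripts the planned measure needed separate mouse and rat values, and a measure of total level was used in its place: per cell the median log2 ratio of X-linked genes at 5 FPKM or more to their mean over the 11 samples, with the sample as the median over its cells. It was tested by an exact permutation test, two-sided, over the 330 splits of the samples. The planned comparisons of mouse with rat alleles in AdESCs, of allelic with parental divergence and of the mouse share of expression were not run for the same reason. The pairing of single-cell samples by line was checked: deviations from the group mean correlated across genes at 0.012 on average for samples of the same line (-0.015 to 0.036, 7 pairs) and at -0.004 for other lines (-0.023 to 0.026, 21 pairs). The main fits therefore had no block, and a fit with the line as a block was an alternative.

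Other alternatives were a pseudocount of 0.1, no filter on low values, quantile and upper-quartile scaling, a log2 change of at least 1 on top of the threshold, the mean of log2 values over cells, other groupings in the fit, and leaving out each line or sample in turn. The pipeline was tested on simulated data with 100 genes changed by a log2 of 1 or 2 in each comparison. False calls in these data were 4 against mouse, 0 against rat, 2 between species, 5 against the parental mean, 1 between RM and MR, 2 for all differentiated cells, and 0 for EB and for testis cells. Values were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.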

Results

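RNA was measured by sequencing in mouse-rat allodiploid embryonic stem cells (AdESCs), which hold a haploid mouse genome and a haploid rat genome in 1 nucleus. The bulk set held 8 libraries of stem cells in G0/G1, 1 per line: mouse ESC lines F145 and F146, rat ESC lines DA25 and DA53, and AdESC lines RM1-1, RM2-1, MR1-1 and MR2-1. The single-cell set held 87 cells of the same 4 AdESC lines in 11 samples, a sample being the cells of 1 type from 1 line. AdESC cells made up 24 of them, and 63 came from embryoid bodies (EB, aggregates of differentiating stem cells) or from fibroblasts, neurons, lung and somatic testis of chimaeric animals. Values were FPKM, which scales fragments to transcript length and library size, for 13926 mouse-rat homologues on the builds mm10 and rn5. Summed FPKM ran from 312695 to 377664 in the bulk libraries, with 7835 to 8770 genes at 1 FPKM or more, and from 213045 to 411555 in the cells, with 3444 to 6246 such genes. Bulk FPKM are given as mean ± SD over lines, and single-cell FPKM as mean ± SD over samples. Each log2 difference is the fitted change of log2(FPKM + 1) ± SE, so where a gene stands near 0 in a group the added 1 sets its size.

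Whether AdESCs keep the transcriptome of a normal stem cell was addressed by setting the 4 AdESC lines against the mouse lines (n = 2). Dnmt3l (chromosome 10), the cofactor of the de novo DNA methyltransferases, rose from 44.5 ± 6.76 to 340.0 ± 81.8 FPKM, a log2 difference of 2.88 ± 0.30 (adjusted p = 0.00124). Epcam (chromosome 17), an epithelial adhesion molecule, rose from 31.1 ± 9.03 to 203 ± 37.1 FPKM (2.68 ± 0.26, adjusted p = 0.000705). Pcolce (chromosome 5), an enhancer of procollagen cleavage, fell from 64.5 ± 2.52 to 8.06 ± 1.54 FPKM (-2.87 ± 0.30, adjusted p = 0.00123). The pluripotency factors Pou5f1 (709.6 ± 66.5 against 542 ± 151 FPKM, adjusted p = 0.363), Nanog (244 ± 50.8 against 454 ± 184, adjusted p = 0.151) and Sox2 (46 ± 30.1 against 60.9 ± 4.36, adjusted p = 0.552) did not pass the test. Nor did the imprinted RNA H19 (29.3 ± 16.9 against 92.4 ± 96.2 FPKM, adjusted p = 0.385).

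Of 8794 genes tested, 238 were higher and 104 lower in AdESCs than in mouse ESCs, 342 in all. The groups did not overlap in any of the 342, as the selection all but ensures. In both mouse lines 10 of the genes that rose were listed at 0. Among those were the Fc receptor-like gene Fcrla, at 78.8, 171, 76.5 and 168 FPKM in MR1-1, MR2-1, RM1-1 and RM2-1, and the X-linked vesicle fusion gene Vamp7, at 13.3, 18.7, 13.4 and 14.5 FPKM. The largest other rises included Ramp2, a partner of the adrenomedullin receptor (0.65 ± 0.24 to 37.9 ± 11.1 FPKM), the lysophosphatidic acid receptor Lpar2 (3.77 ± 0.29), the complement regulator Cd59b (3.69 ± 0.32) and Tex19.2, a germline gene (3.65 ± 0.61). Large falls included Pla2g1b, a secreted phospholipase (-3.65 ± 0.42), Ddc, which makes dopamine from DOPA (-2.95 ± 0.37), Tspo, an outer mitochondrial membrane protein (-2.46 ± 0.31), and the protease inhibitor A2m (-2.36 ± 0.47). Without F145 the count was 186 (98 up, 88 down), without DA25 or DA53 it was 151 (119 up, 32 down), without MR2-1 151 and without RM1-1 173. With a pseudocount of 0.1 the split was 297 up and 55 down, and without the filter on low values 159 up and 152 down. With RM and MR as separate groups the count was 156 (118 up, 38 down).

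X-linked genes were higher in AdESCs as a list: of 201 tested, 21 rose and 1 fell over all genes, and 48 rose and 3 fell adjusted over the list alone (median 0.53, adjusted p = 4.41e-11). That call was lost with an estimated correlation (adjusted p = 0.596), and stayed with each bulk library left out in turn (adjusted p at most 6.51e-07). Members that rose included C1galt1c1, a chaperone of O-glycosylation (3.99 ± 0.257 to 28.5 ± 9.08 FPKM), the prefoldin-like Uxt (2.1 ± 0.35), Pnma3 (1.86 ± 0.37) and the transcriptional repressor Nkap (1.19 ± 0.25). Itm2a, a membrane protein of muscle and cartilage, fell (-1.82 ± 0.36). Genes listed as X escape gave 1 rise in 11, and 5 adjusted over the list alone. Their median was 0.57 (adjusted p = 0.0298, or 0.596 with an estimated correlation). They were not called without F146 (adjusted p = 0.328) or RM1-1 (0.0739). The DNA methylation list gave 2 rises in 11, Dnmt3l among them, and 3 adjusted over the list alone (median 0.67, adjusted p = 0.0137, and adjusted p = 0.596 with an estimated correlation), and was not called without F146 (median 0.24, adjusted p = 0.368).

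Germ cell genes rose in 2 of 9 (6 up and 1 down adjusted over the list alone, adjusted p = 0.0131), namely Piwil2, a piRNA-binding protein (2.78 ± 1.83 to 18.8 ± 7.53 FPKM), and the germline helicase Ddx4 (2.18 ± 0.52). Primed epiblast genes gave 1 rise in 12 (6 up and 1 down adjusted over the list alone, adjusted p = 0.011), the tight junction gene Cldn6 (2.52 ± 0.32). The lung epithelial list rose in 2 of 6 (3 adjusted over the list alone, adjusted p = 0.0131), which were Epcam and Pdpn (2.39 ± 0.34), both surface proteins of many epithelia rather than of lung alone. The glial list rose in 1 of 5, over all genes and adjusted over the list alone, the myelin gene Mog (0.31 ± 0.113 to 8.39 ± 1.94 FPKM, list adjusted p = 0.0332). With an estimated correlation each of these calls was lost (adjusted p = 0.596). Leaving out a library also ended them: the germ cell call without F145 (adjusted p = 0.39), RM2-1 (0.185), RM1-1 (0.0887), DA25 or DA53 (0.105 for both), the primed epiblast call without F146 (0.247) or MR1-1 (0.0512), and the lung epithelial call without F145 (0.222). The glial call was lost without F146 (0.379), RM2-1 (0.108), DA53 (0.105) or MR1-1 (0.0819). Lin28a, which blocks let-7 processing, rose in the naive pluripotency list (2.34 ± 0.53), the only member of 19 to pass, over all genes or adjusted over the list alone (list adjusted p = 0.188). Among paternally expressed imprinted genes Snurf (2.21 ± 0.27) and Nnat (2.15 ± 0.37) rose, and among maternally expressed ones Grb10 fell (18.8 ± 12.6 to 3.75 ± 1.62 FPKM), with neither list called (adjusted p = 0.615 and 0.188).

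Interferon response genes fell in 2 of 14 (5 adjusted over the list alone, median -1.51, adjusted p = 0.000265, and adjusted p = 0.596 with an estimated correlation). They were Bst2, which tethers budding virus (247 ± 44.7 to 62.8 ± 22.2 FPKM), and Usp18, which removes ISG15 (-2.79 ± 0.50). Oas2, the antiviral oligoadenylate synthetase, fell too (-2.55 ± 0.37). Fibroblast markers moved with them: no member of the fibroblast list passed over all genes by limma, against 1 up and 9 down of 28 adjusted over the list alone (median -1.42, adjusted p = 7.95e-06). The feeder fibroblast list gave 0 over all genes and 6 falls of 10 adjusted over the list alone (median -2.18, adjusted p = 4.43e-05). The stroma list gave 0 and 2 of 6 (adjusted p = 0.026), and the leukocyte list 0 of 7 either way (adjusted p = 0.037). With an estimated correlation these calls were lost as well (adjusted p = 0.596). They rested on F145: without it the adjusted p was 0.236 for the interferon list (median -0.45), 0.99 for the fibroblast list (median -0.31), 0.348 for the feeder list (median -0.91) and 0.628 for the stroma list, and the leukocyte list had too few members past the filter. The fibroblast list averaged 6.02 on the log2(FPKM + 1) scale in F145 and 3.57 in F146, against 2.91 to 3.79 in the AdESC lines, and the leukocyte list 2.93 and 1.16, against 0.79 to 1.24. Col1a1 stood at 641 FPKM in F145 and 89.7 FPKM in F146, against 50.7 ± 31.3 in AdESCs (adjusted p = 0.141), so the spread between the mouse lines was as large as the difference. In simulated data the fit recovered 5 of 100 genes changed by a log2 of 1 and 57 of 100 changed by 2.

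**Figure D1:**
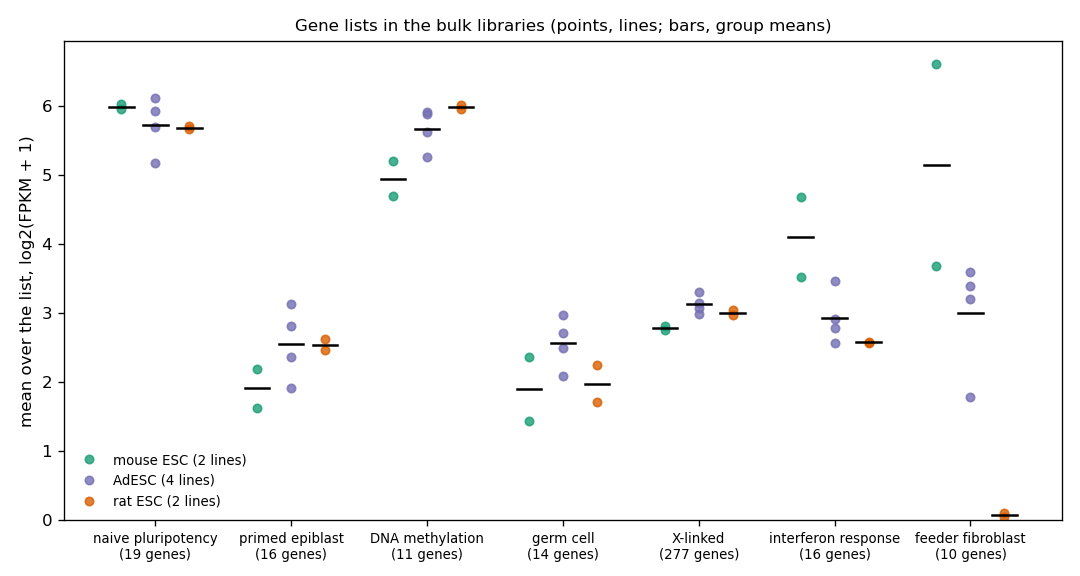
Mean log2(FPKM + 1) of fixed gene lists in each bulk library, with points for the lines of mouse ESCs, rat ESCs and AdESCs. The feeder fibroblast list stood at 6.61 in F145 and 3.69 in F146, at 0.11 or less in the rat lines and between 1.78 and 3.60 in the AdESC lines.

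Against the rat lines (n = 2) the same 4 AdESC lines differed most in genes that the rat libraries listed at or near 0. The heat shock protein Hspb1 (chromosome 5) stood at 344 ± 84.5 FPKM in AdESCs and 0.962 ± 0.328 in rat ESCs (7.44 ± 0.30, adjusted p = 2.42e-07). The tetraspanin Cd81 (chromosome 7), a maternally expressed imprinted gene of the mouse, rose from 4.67 ± 1.63 to 113 ± 29.3 FPKM (4.32 ± 0.36, adjusted p = 4.54e-05). Car6 (chromosome 4), a secreted carbonic anhydrase, fell from 195 ± 4.97 to 10.8 ± 3.29 FPKM (-4.09 ± 0.30, adjusted p = 2.05e-05). Lefty1 (chromosome 1), an inhibitor of Nodal signalling, fell from 313 ± 31.1 to 50.4 ± 61 FPKM (-3.39 ± 0.87, adjusted p = 0.0367). Nanog (244 ± 50.8 against 244 ± 38.2 FPKM, adjusted p = 0.979), Pou5f1 (adjusted p = 0.48), Sox2 (adjusted p = 0.577) and H19 (adjusted p = 0.301) did not pass.

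The fit called 853 genes of 8794, with 509 higher in AdESCs and 344 lower, and the groups did not overlap in any of them. Of those that rose, 117 were listed at 0 in both rat lines. Rpl7a, a protein of the large ribosomal subunit, was among these and stood at 701, 662, 811 and 718 FPKM in MR1-1, MR2-1, RM1-1 and RM2-1, and the glucose transporter Slc2a3 was at 315, 266, 213 and 364. Other rises included Rps19 (7.54 ± 0.30), the nucleosome-binding Hmgn1 (7.24 ± 0.28) and Mylpf, a light chain of muscle myosin (6.67 ± 0.45), of which Rps19 and Hmgn1 stood below 0.2 FPKM in rat. Further falls were the steroid dehydrogenase Akr1c14 (-4.57 ± 0.71), the interferon-induced GTPase Gbp2 (-4.19 ± 0.46), the glycogen-binding Stbd1 (-3.81 ± 0.39), the Notch target Hey2 (-3.36 ± 0.36) and the kinase Camk4 (-3.30 ± 0.33). Without either rat line the count fell. With a pseudocount of 0.1 the split was 741 up and 308 down. Upper-quartile scaling moved the median of all genes by 0.12, from -0.11 to 0.02.

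The fibroblast list was higher in AdESCs, with 10 of 28 up over all genes and 15 adjusted over the list alone (median 2.17, adjusted p = 2.35e-07, and adjusted p = 0.89 with an estimated correlation). The feeder list gave 5 of 10, and 6 adjusted over the list alone (median 2.94, adjusted p = 2.61e-05, or 0.857 with an estimated correlation). Vim, a mesenchymal filament, stood at 61.5 ± 31.9 FPKM in AdESCs and 0.456 ± 0.0209 in rat, and Col1a1 at 50.7 ± 31.3 and 0.058 ± 0.0198. In single-cell AdESC samples the feeder list averaged a log2 of 0.17 or less, so its bulk values may not be AdESC expression. Ribosomal protein genes gave 5 of 42 up, over all genes and adjusted over the list alone (median 0.15, adjusted p = 0.0143, and adjusted p = 0.89 with an estimated correlation). With upper-quartile scaling the ribosomal median was 0.29. The 5 genes ran from Rpl28 (351 ± 2.09 to 1069 ± 263 FPKM) to those near 0 in rat. Maternally expressed imprinted genes gave 4 of 11 up, over all genes and adjusted over the list alone (median 1.02, adjusted p = 0.0143, and adjusted p = 0.637 with an estimated correlation), among them Cd81, Grb10 (1.76 ± 0.44) and Tssc4 (1.61 ± 0.30). The Sertoli list gave 2 of 8, over all genes and adjusted over the list alone (median 1.39, adjusted p = 0.0143, and adjusted p = 0.637 with an estimated correlation). These were the secreted chaperone Clu (1.59 ± 0.357 to 25.3 ± 12.0 FPKM) and the glutathione transferase Gstm6 (1.88 ± 0.43), neither of them made by Sertoli cells alone.

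Naive pluripotency genes moved both ways against rat, with 3 of 19 up and 1 down over all genes and 3 up and 4 down adjusted over the list alone (list adjusted p = 0.71). Fbxo15, a target of Pou5f1 and Sox2, rose from 1.91 ± 0.375 to 81.4 ± 27.8 FPKM, and the nuclear receptors Nr0b1 (3.93 ± 0.64) and Nr5a2 (2.42 ± 0.59) rose. The LIF receptor Lifr fell from 102 ± 14.3 to 20.6 ± 10.8 FPKM. The paternally expressed Snrpn rose (3.06 ± 0.50) while Nnat (-1.91 ± 0.37) and Snurf (-1.03 ± 0.27) fell (list adjusted p = 0.746). X-linked genes gave 21 up and 11 down of 201, and 24 up and 12 down adjusted over the list alone (adjusted p = 0.742). The median and the mean differed in sign for the X-linked (-0.08 and 0.15), naive pluripotency (-0.36 and 0.05), glycolysis (-0.5 and 0.1), interferon (-0.12 and 0.35), unfolded protein response (-0.07 and 0.14) and visceral endoderm lists (0.34 and -0.08), none of them called. In simulated data 8 of 100 genes changed by a log2 of 1 and 63 of 100 changed by 2 were recovered.

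The parent species themselves (n = 2 lines each) give the background for both comparisons. Rat ESCs held more Car6 (195 ± 4.97 against 0.683 ± 0.36 FPKM, 6.88 ± 0.35, adjusted p = 1.11e-06) and more Ramp2 (152 ± 13.7 against 0.65 ± 0.243 FPKM). They also held more Lefty1 (313 ± 31.1 against 2.42 ± 0.0442 FPKM) and Efna1, an ephrin ligand (5.37 ± 0.51). Hspb1 (-7.72 ± 0.34, adjusted p = 4.95e-07) and Hmgn1 (-7.85 ± 0.32) stood near 0 in rat, so lower expression is not shown. Pou5f1 (863 ± 85.9 against 542 ± 151 FPKM, adjusted p = 0.0829), Nanog (adjusted p = 0.0998), Sox2 (adjusted p = 0.904) and H19 (adjusted p = 0.98) did not pass. In total 1239 genes were higher in rat and 1104 lower, 2343 of 8794, and 172 of them had a species at 0. Without either rat line the count fell. Upper-quartile scaling moved the median of all genes from 0.08 to -0.05. The simulated recovery was 1 of 100 at a log2 of 1 and 32 of 100 at 2.

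Between the species the fibroblast list fell in rat in 18 of 28 and rose in 1 (23 and 2 adjusted over the list alone, median -3.23, adjusted p = 4.02e-08). The feeder list fell in 9 of 10, and in 10 adjusted over the list alone (median -5.1, adjusted p = 4.28e-06). Both calls were lost with an estimated correlation (adjusted p = 0.748). X-linked genes gave 61 up and 24 down of 201 (64 and 26 adjusted over the list alone, adjusted p = 0.00946). Leukocyte genes gave 2 down of 7 (5 adjusted over the list alone, adjusted p = 0.0198), among them the macrophage genes Cd68 (-3.19 ± 0.60) and Laptm5 (-2.50 ± 0.56). With an estimated correlation both were lost (adjusted p = 0.765). Interferon genes gave 1 up and 4 down of 14 (2 and 9 adjusted over the list alone, adjusted p = 0.029), with Bst2 (247 ± 44.7 to 1.36 ± 1.05 FPKM) and Ifitm3 (-2.82 ± 0.62). Maternally expressed imprinted genes gave 4 falls of 11, over all genes and adjusted over the list alone (adjusted p = 0.029), with Cd81 (-5.17 ± 0.41) and Grb10 (-3.73 ± 0.51). Targets of p53 gave 5 falls of 17, over all genes and adjusted over the list alone (adjusted p = 0.0318), with Btg2 (-3.72 ± 0.79) and the cell-cycle inhibitor Cdkn1a (146.3 ± 78.2 to 32.5 ± 0.178 FPKM). DNA methylation genes gave 4 rises and 1 fall of 11 (6 and 1 adjusted over the list alone, adjusted p = 0.0354), with Dnmt3l (3.37 ± 0.35) and Dnmt3a (2.06 ± 0.50) up and the imprint-protecting factor Zfp57 down (-1.71 ± 0.48). The calls of these last lists, too, were lost with an estimated correlation (adjusted p = 0.748). Median, mean and test differed in sign for the naive pluripotency, trophoblast, unfolded protein response, oxidative phosphorylation, X escape, neuron and glial lists, none of them called.

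Whether AdESCs lie outside the average of their parents was addressed by testing them against the mean of the mouse and rat log2 values, with the 3 groups in 1 fit. Hmga2 (chromosome 10), a chromatin protein of fetal growth, stood at 16.9 ± 4.61 FPKM in AdESCs and 3.26 ± 3.38 over the 4 parental lines (2.49 ± 0.26, adjusted p = 0.000864). Acot1 (chromosome 12), a cytosolic acyl-CoA thioesterase (1.77 ± 1.43 to 7.75 ± 1.21 FPKM, 1.82 ± 0.25, adjusted p = 0.00536), was higher too. So were the incretin hormone gene Gip (2.21 ± 0.31, adjusted p = 0.00668) and the meiotic recombinase Dmc1 (1.48 ± 0.25, adjusted p = 0.0183). Mras (chromosome 9), a Ras-related GTPase, was lower (9.88 ± 2.83 to 1.87 ± 0.307 FPKM, -1.88 ± 0.27, adjusted p = 0.00697), as were the interferon-induced Ifi35 (-1.39 ± 0.28) and the G-protein subunit Gng10 (-1.19 ± 0.23). Pou5f1 (adjusted p = 0.956), Nanog (adjusted p = 0.638), Sox2 (adjusted p = 0.775) and H19 (adjusted p = 0.535) did not pass.

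The fit called 106 genes above and 6 below the parental mean. In 16 of them (13 up, 3 down) AdESC and parental lines did not overlap, which chance gives for 2.9% of genes taken without a test. The 13 included Clu (2.35 ± 0.37), Tfr2, an iron sensor (1.92 ± 0.32), the lysosomal amidase Naaa (1.82 ± 0.34), Sema7a (1.79 ± 0.33), Ripk4 (1.52 ± 0.29) and Miox (1.39 ± 0.27). The count rested on the scale and on the genes at 0: with the parental mean taken on linear FPKM it was 2, both down. Without genes listed at 0 in a species it was 41 (38 up, 3 down), an alternative chosen after seeing the data. With a pseudocount of 0.1 it was 240, and with the parents as a single group of 4 lines it was 0 by limma, with 280 at an unadjusted p under 0.05. Without DA53 it was 56, without DA25 65, without MR2-1 68 and without RM1-1 71. In simulated data 31 of 100 genes changed by a log2 of 1 and 78 of 100 changed by 2 were recovered.

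X-linked genes gave 6 of 201 above the parental mean, and 12 adjusted over the list alone (median 0.27, adjusted p = 1.52e-09, and adjusted p = 0.497 with an estimated correlation). Hprt, which salvages purines (47.4 ± 9.55 against 35.2 ± 41.4 FPKM over the parental lines), Bex4 and the ubiquitin ligase Rlim were among them, and all 3 were listed at 0 in both rat lines. Ribosomal protein genes gave 4 of 42, and 6 adjusted over the list alone (median 0.14, adjusted p = 2.74e-05, and adjusted p = 0.709 with an estimated correlation). Rps15a stood at 974 ± 99.9 against 663 ± 618 FPKM (1.22 ± 0.21), while Rpl7a, Rps9 and Rps19 stood at or near 0 in rat and below the parental mean in linear FPKM. Germ cell genes gave 1 of 9 (4 up and 1 down adjusted over the list alone, adjusted p = 0.00162, and adjusted p = 0.709 with an estimated correlation), the synaptonemal protein Sycp1 (1.96 ± 0.40). The glial list gave 0 by limma over all genes and 4 of 5 adjusted over the list alone (median 1.22, adjusted p = 0.000474). The X escape list gave 1 of 11, over all genes and adjusted over the list alone (adjusted p = 0.00159), and the Sertoli list 1 of 8, over all genes and adjusted over the list alone (adjusted p = 0.00241), which was Clu. The glial, X escape and Sertoli calls were lost with an estimated correlation (adjusted p = 0.497). Primed epiblast (Cldn6, 1.41 ± 0.26) and lung epithelial genes (Epcam, 1.42 ± 0.21) each had 1 member up, over all genes and adjusted over the list alone (adjusted p = 0.0212 for both lists). With an estimated correlation they were lost (adjusted p = 0.811 and 0.709). The fibroblast list was not called here (adjusted p = 0.166). The median, the mean and the test differed in sign for the neuroectoderm, glycolysis, G1/S, neuron, leukocyte, stroma and visceral endoderm lists, none of them called.

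Each gene was also placed by which parent AdESCs differed from. AdESCs differed from rat alone in 749 genes (107 listed at 0 in a species) and from mouse alone in 238 (11 listed at 0). They lay between the parents in 99, above both in 4 and below both in 1, and in 7703 they differed from neither, though the parents differed in 1346 of these. Tfr2 (0.26 FPKM in mouse, 1.04 in rat and 5.27 in AdESCs), Naaa (2.77, 4.56 and 16.4), Gip (0.24, 2.25 and 8.82) and Miox (0.05, 0.28 and 2.11) were above both parents, and Mras (10.5, 9.28 and 1.87) was below both. Genes between the parents included Car6 (10.8 FPKM), Pcolce (8.06), Bst2 (62.8), Ramp2 (37.9), the peroxidase Gpx2 (31.4 in mouse, 530.3 in rat and 134 in AdESCs), the imprinted Nnat (3.17, 68.3 and 17.6) and the growth regulator Grb10 (18.8, 0.35 and 3.74). Independent lists would give 15.3 between, 13.8 above and 4.1 below, but the calls share AdESC lines. Simulated unchanged groups gave 0 in each.

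The AdESC lines named RM and MR (n = 2 each) were compared to ask whether lines of either name differ in expression. Sox2 was 25.2 ± 14.4 FPKM in RM and 66.7 ± 28.1 in MR (-1.42 ± 0.45, adjusted p = 1). The imprinted Phlda2 stood at 2.29 and 22.5 FPKM, with an SD of 27.9 in MR, and Krt19, a keratin of simple epithelia, at 25.7 and 76.7 FPKM. Pou5f1 (686 ± 15.1 against 734 ± 104 FPKM), Nanog (214 ± 54 against 274 ± 34.9) and H19 (28.8 ± 22 against 29.7 ± 19.3) did not pass either (adjusted p = 1 for each). By limma 0 of 8794 genes passed, with 51 at an unadjusted p under 0.05, and the test had little reach: 0 of 100 simulated genes changed by a log2 of 1 and 1 of 100 changed by 2 were recovered.

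Between RM and MR 18 lists were called with the preset correlation and none with an estimated one. From here on a value marked estimated is the adjusted p of a list with an estimated correlation. The feeder list was higher in RM (10 of 10 members, median 0.81, adjusted p = 1.85e-05, and adjusted p = 0.404 with an estimated correlation). It averaged 1.78 in MR1-1, 3.4 in MR2-1, 3.6 in RM1-1 and 3.21 in RM2-1, so only MR1-1 stood apart and MR2-1 lay above RM2-1. The fibroblast list was alike, at 2.91, 3.61, 3.79 and 3.48 in the same order. With the feeder list moved the p53 targets (median 0.38, adjusted p = 3.03e-05, estimated 0.256), fibroblast genes (0.2, 3.03e-05, estimated 0.53), ribosomal proteins (0.11, or 0.05 with quantile and 0.19 with upper-quartile scaling, 0.000125, estimated 0.47) and germ cell genes (0.49, 0.000376, estimated 0.404). Lists with smaller calls in that direction were X-linked genes (adjusted p = 0.00133, estimated 0.482), leukocyte genes (0.00534, estimated 0.47) and oxidative phosphorylation (0.00562, estimated 0.53). Myoid genes (0.00173), interferon genes (0.00187), stroma genes (0.00211) and X escape genes (0.00493) moved the same way, with an estimated adjusted p of 0.404 for each. Lower in RM were glycolysis genes (-0.29, adjusted p = 0.000125, estimated 0.386) and primed epiblast genes (-0.51, 0.00133, estimated 0.455). Lower too were lung epithelial genes (-0.3, 0.00173), mesoderm and endoderm genes (-0.35, 0.0141), glial genes (-0.49, 0.0178) and trophoblast genes (-0.29, 0.0437), with an estimated adjusted p of 0.404 for each. Adjusted over the list alone 0 genes passed by limma in each, except Hand1, a factor of trophoblast and mesoderm held in both those lists, which fell from 5.47 to 0.249 FPKM. For the maternally expressed imprinted, Wnt target, G1/S and visceral endoderm lists, none of them called, the median or the mean pointed away from the test.

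What AdESC cells lose and gain as they differentiate was addressed in single cells, with 7 differentiated samples against 4 AdESC samples and each sample summarised by the mean FPKM of its cells. Nanog fell from 492.5 ± 116 to 0.085 ± 0.0491 FPKM (-8.80 ± 0.34, adjusted p = 3.74e-10) and Pou5f1 from 77.9 ± 10.1 to 1.29 ± 2.61 FPKM (-5.58 ± 0.57, adjusted p = 1.12e-05). Sox2, which neural progenitors also need, fell from 35.4 ± 9.71 to 3.99 ± 6.87 FPKM (-3.99 ± 0.82, adjusted p = 0.00404), and stayed at 11.3 FPKM in the neuron sample and 16.3 in RM1-1 testis. Id1 (chromosome 2), a target of BMP signalling, rose from 1.68 ± 0.46 to 118.5 ± 38.5 FPKM (5.43 ± 0.32, adjusted p = 3.39e-08). Vim rose from 7.36 ± 7.35 to 1116 ± 1019 FPKM (6.99 ± 0.75, adjusted p = 1.59e-05), and Tagln, an actin-binding protein of smooth muscle, from 0.055 ± 0.0542 to 1087 ± 1509 FPKM (8.29 ± 1.07, adjusted p = 8.93e-05). H19 did not pass (1.47 ± 1.88 to 29 ± 47.8 FPKM, adjusted p = 0.398).

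Of 8421 genes tested, 621 rose and 722 fell, 1343 in all, 90 of them listed at 0 in a group. In 937 (390 up, 547 down) no sample overlapped with the other group. Large rises also came from the clotting initiator F3 (6.07 ± 0.95), the myosin light chain Myl9 (5.62 ± 0.90), the small heat shock protein Cryab (5.62 ± 0.89), the lipid-binding Anxa5 (5.50 ± 0.46) and the microfibril gene Mfap2 (5.49 ± 0.70). Large falls came from Hprt (181 ± 35.9 to 0.014 ± 0.0177 FPKM), the thyrotropin-releasing hormone gene Trh (-7.37 ± 0.59), and the TGF-beta ligand Gdf3 (-7.33 ± 0.37). Further falls were Pramel6 (-7.17 ± 0.38), the threonine dehydrogenase Tdh (-6.84 ± 1.08), Bex4 (-6.80 ± 0.38) and Lefty1 (-6.56 ± 0.45). Without the AdESC samples of MR1-1, MR2-1, RM1-1 or RM2-1 the count was 807, 826, 791 and 826. Taking the mean of log2 values over cells gave 456 up and 1152 down and moved the median of all genes by -0.12, from 0.02 to -0.1. In simulated data 5 of 100 genes changed by a log2 of 1 and 30 of 100 changed by 2 were recovered.

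Naive pluripotency genes fell in 13 of 19, and in 16 adjusted over the list alone (median -4.12, adjusted p = 1.22e-15), a call that held with an estimated correlation (adjusted p = 0.00486). Among them was Tfcp2l1, a factor of the naive network (116 ± 25.2 to 1.24 ± 1.22 FPKM). Germ cell genes fell in 8 of 9, over all genes and adjusted over the list alone (median -3.7, adjusted p = 8.3e-09), and this held too (adjusted p = 0.00409 with an estimated correlation). With the mean of log2 values over cells the germ cell median was -2.3. Dazl, an RNA-binding protein of germ cells (97.8 ± 85.4 to 0.523 ± 1.37 FPKM), and Ddx4 (-4.06 ± 0.59) were among these. DNA methylation genes fell in 5 of 10 (1 up and 6 down adjusted over the list alone, median -1.71, adjusted p = 0.00841, and adjusted p = 0.261 with an estimated correlation). They were led by Dnmt3l (218 ± 45.4 to 15.8 ± 27 FPKM), Zfp57 (-3.36 ± 0.42), the KRAB co-repressor Trim28 (-2.74 ± 0.38) and Dnmt3b (-2.65 ± 0.73). Polycomb and chromatin genes fell in 4 of 15, over all genes and adjusted over the list alone (median -0.54, adjusted p = 0.0221, and adjusted p = 0.28 with an estimated correlation). Among these were the polycomb proteins Cbx7 (-2.81 ± 0.43) and Eed (69.7 ± 10.2 to 21 ± 6.25 FPKM). The trophoblast list fell in 2 of 5, and 3 adjusted over the list alone (adjusted p = 0.0231, and adjusted p = 0.261 with an estimated correlation or 0.104 with the line as a block). Its member Tfap2c (-3.70 ± 0.46) is also a germline factor.

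Lists of the cell cycle and of glycolysis fell over the 7 samples together. G1/S genes gave 8 of 19, and 12 adjusted over the list alone (median -1.29, adjusted p = 1.86e-05, and adjusted p = 0.341 with an estimated correlation), such as the replication factors Cdt1 (32.6 ± 17.8 to 4.63 ± 4.03 FPKM) and Mcm2 (-2.06 ± 0.49). G2/M genes gave 2 of 17, and 1 adjusted over the list alone (median -1.38, adjusted p = 0.00138, and adjusted p = 0.659 with an estimated correlation), which were the mitotic regulators Cdc20 (-2.45 ± 0.69) and Aurka (-1.98 ± 0.62). The G2/M list did not fall in every sample: it averaged 6.42 in RM1-1 EB and 6.06 in the neuron sample, against 5.88 to 6.31 in AdESC samples, and 5.34 in RM1-1 testis, 4.61 in MR2-1 EB, 4.37 in RM2-1 testis, 3.09 in fibroblasts and 2.61 in lung. Glycolysis genes gave 5 of 14, and 6 adjusted over the list alone (median -0.84, adjusted p = 0.00493, and adjusted p = 0.28 with an estimated correlation). Falls came from Slc2a3 (-3.74 ± 0.87), the pyruvate kinase Pkm (1619 ± 203 to 534 ± 146.4 FPKM) and hexokinase Hk2 (-1.47 ± 0.35). Ribosomal protein genes gave 3 of 42, and 0 by limma adjusted over the list alone (median -0.31, adjusted p = 0.000478, and adjusted p = 0.699 with an estimated correlation), with Rps2 (-0.75 ± 0.21) and Rpl14 (-0.64 ± 0.17). With the mean of log2 values over cells the G1/S median was -2.05, and with quantile scaling the ribosomal median was -0.12. X-linked genes gave 17 up and 51 down of 203 (20 and 66 adjusted over the list alone, median -0.56, adjusted p = 0.000524, and adjusted p = 0.115 with an estimated correlation). Rlim (17.6 ± 9.15 to 0.00967 ± 0.0103 FPKM) and the deubiquitinase Usp9x (-1.98 ± 0.35) fell, and the proteoglycan Bgn rose (4.73 ± 1.47). X escape genes gave 1 up and 5 down of 12 (1 and 6 adjusted over the list alone, adjusted p = 0.0285, and adjusted p = 0.19 with an estimated correlation), with Utp14a (-1.53 ± 0.38).

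Mesenchymal lists rose. Fibroblast genes gave 10 of 27 up, and 14 adjusted over the list alone (median 2.22, adjusted p = 5.68e-08, and adjusted p = 0.28 with an estimated correlation). Examples are Fstl1 (21 ± 9.74 to 428 ± 408 FPKM), S100a6 (3.84 ± 1.01) and Col1a2 (3.31 ± 1.08). Stroma genes gave 4 of 11, and 6 adjusted over the list alone (median 2.49, adjusted p = 0.000291, and adjusted p = 0.115 with an estimated correlation). They included the mesenchymal nuclear receptor Nr2f2 (0.169 ± 0.338 to 20.0 ± 9.56 FPKM), the chemokine Cxcl12 (4.05 ± 1.05) and Igf1 (2.62 ± 0.75). The feeder list gave 4 of 10, and 6 adjusted over the list alone (median 2.65, adjusted p = 0.00127). The myoid list gave 4 of 9, and 5 adjusted over the list alone (median 2.33, adjusted p = 0.00178), with Tpm2 (4.13 ± 1.19) and Cnn1 (3.70 ± 1.10). With an estimated correlation the feeder and myoid calls were lost (adjusted p = 0.395). With the mean of log2 values over cells these medians were smaller, at 1.39 for the fibroblast, 1.59 for the stroma, 1.62 for the feeder and 1.35 for the myoid list. Neuron and glial genes averaged 3.26 in the neuron sample and 2.31 in RM1-1 testis, and 0.89 or less in the other differentiated samples. Over all samples the neuron (1 up and 1 down of 13, adjusted p = 0.63), glial (2 up and 1 down of 11, adjusted p = 0.129) and neuroectoderm lists (1 down of 4, adjusted p = 0.862) were not called.

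Imprinted genes moved both ways. Among paternally expressed ones Nnat (1.07 ± 0.362 to 36.3 ± 40.02 FPKM) and Ndn, a growth suppressor of neurons (4.66 ± 4.50 to 81.6 ± 78.1 FPKM), rose and Snrpn fell (-1.27 ± 0.41), with 9 tested (adjusted p = 0.357). Among the 13 maternally expressed ones Osbpl5 (2.34 ± 0.51) and Cd81 (93.5 ± 17.6 to 289.5 ± 139 FPKM) rose and Igf2r fell (-1.65 ± 0.54, list adjusted p = 0.282). With the line as a block the mesoderm and endoderm list (adjusted p = 0.0688) and the Sertoli list (adjusted p = 0.0761) passed, at 0.00963 and 0.0214. No call was made for cholesterol synthesis (adjusted p = 0.129), MAPK targets (0.104), Wnt targets (0.63), p53 targets (0.696), the unfolded protein response (0.63), oxidative phosphorylation (0.862), interferon response (0.871) or primed epiblast genes (0.286). The Leydig (adjusted p = 0.377), lung epithelial (0.424), visceral endoderm (0.439), endothelial (0.439), cardiac muscle (0.464) and leukocyte lists (0.516, with a median of 0.38 and a mean of -0.93) were not called either.

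**Figure D2:**
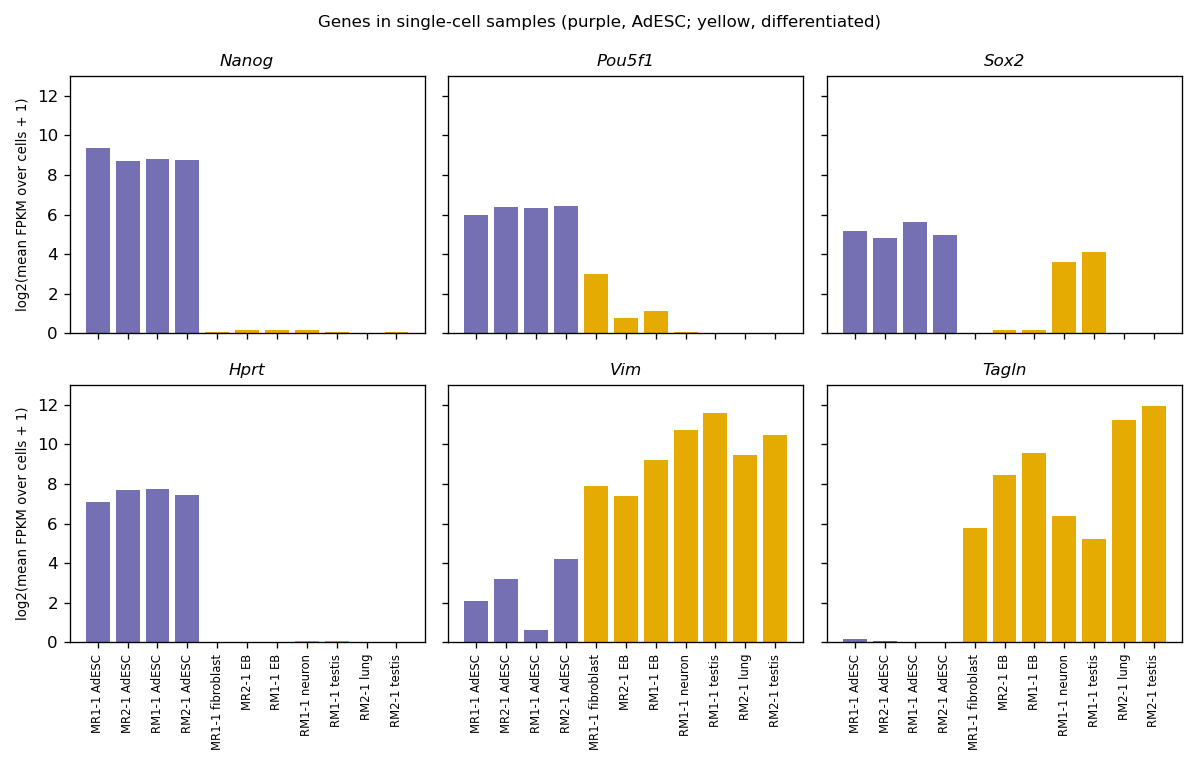
Mean FPKM over cells on a log2(FPKM + 1) scale for named genes in the 11 single-cell samples, 1 bar per sample, with AdESC samples beside differentiated ones. Nanog averaged 492.5 FPKM in AdESC samples and 0.085 in differentiated ones, and Vim 7.36 and 1116.

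**Figure D3:**
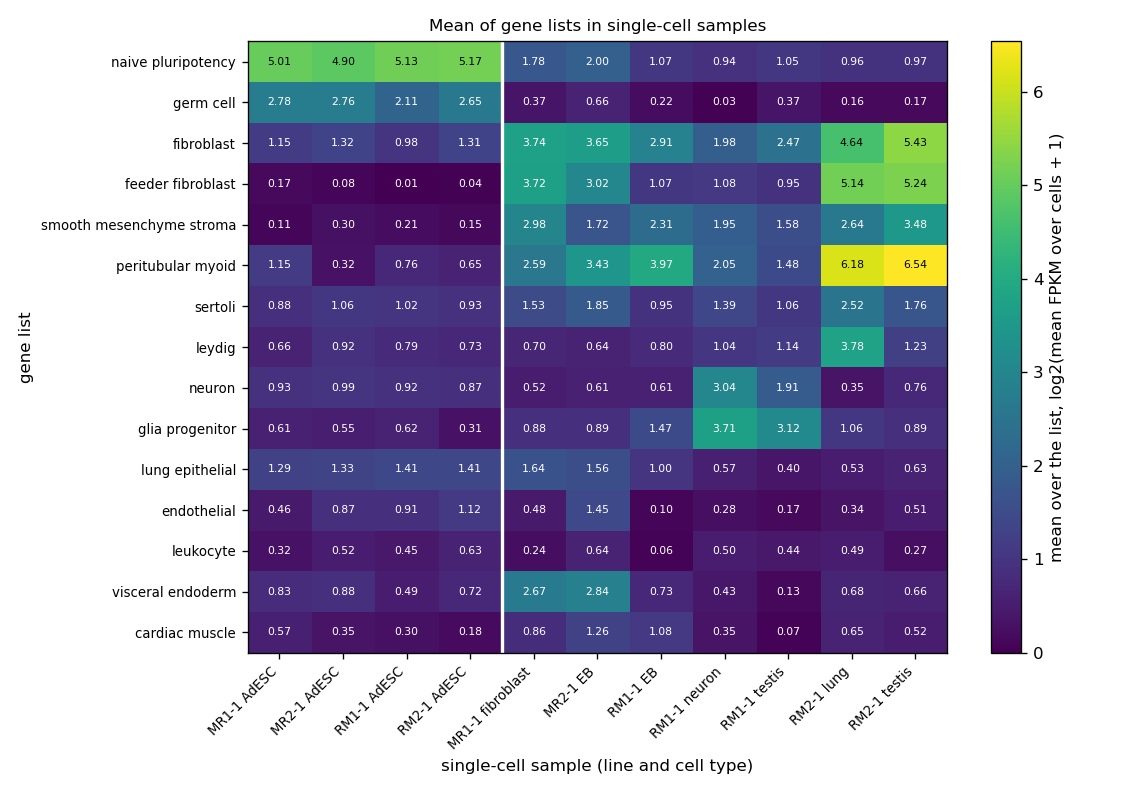
Mean log2(FPKM + 1) of fixed gene lists, 1 line of tiles per list, in each of the 11 single-cell samples, with the value as colour. The myoid list reached 6.54 in RM2-1 testis and 6.18 in RM2-1 lung, and the Leydig list 3.78 in RM2-1 lung.

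In vitro differentiation alone was read from the EB samples (MR2-1 and RM1-1, n = 2) against the 4 AdESC samples. Tnnc1 (chromosome 14), the slow troponin C of heart muscle, rose from 0.074 ± 0.0913 to 112 ± 74 FPKM (6.55 ± 0.57, adjusted p = 0.000673), and Tagln from 0.055 ± 0.0542 to 552 ± 293 FPKM (8.93 ± 1.41, adjusted p = 0.00917). The basement membrane gene Col4a1 (6.05 ± 1.31, adjusted p = 0.0325) and the endoderm factor Gata6 (0.455 ± 0.532 to 45.5 ± 53.9 FPKM, adjusted p = 0.0397) rose too. Tpm1 (5.26 ± 0.93), Vim (5.75 ± 0.90) and the peroxidase Pxdn (4.92 ± 0.71) rose as well. Nanog (-8.74 ± 0.44), Pou5f1 (-5.35 ± 0.48, adjusted p = 0.000682), Sox2 (-4.96 ± 0.98, adjusted p = 0.0218), Hprt (-7.47 ± 0.49) and the metallothionein Mt2 (789 ± 191 to 3.78 ± 1.17 FPKM) fell. H19 did not pass (53.7 ± 72.2 FPKM in EB, adjusted p = 0.162).

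The EB fit called 206 genes up and 261 down, 467 of 8421, of which 85 had a group at 0. With the line as a block the count was 25 (7 up, 18 down). The mean of log2 values gave 169 up and 381 down. Leaving out an AdESC sample gave 222 without MR1-1, 226 without MR2-1, 237 without RM1-1 and 258 without RM2-1, and the simulated recovery was 0 of 100 at a log2 of 1 and 6 of 100 at 2.

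In EBs naive genes fell in 11 of 19, and 14 adjusted over the list alone (median -4.11, adjusted p = 7.63e-13). Germ cell genes fell in 5 of 9, and 8 adjusted over the list alone (median -3.65, adjusted p = 1.2e-06). Both were lost with an estimated correlation (adjusted p = 0.0646). Fibroblast genes rose in 4 of 27, and 5 adjusted over the list alone (median 1.63, adjusted p = 1.08e-05, and adjusted p = 0.56 with an estimated correlation), with Sparc (3.62 ± 0.84) and Fstl1 (2.89 ± 0.60). With the mean of log2 values over cells the fibroblast median was 0.77 and the germ cell median -2.3. Mesoderm and endoderm genes rose in 2 of 12, and 3 adjusted over the list alone (median 2.22, adjusted p = 0.00242, and adjusted p = 0.203 with an estimated correlation). X-linked genes gave 7 up and 27 down of 203 (16 and 44 adjusted over the list alone, adjusted p = 0.000215, and adjusted p = 0.16 with an estimated correlation), with the amino acid transporter Slc7a3 (239 ± 70.3 to 7.67 ± 10.7 FPKM). Ribosomal protein genes gave 0 by limma either way (median -0.16, adjusted p = 0.0178, and adjusted p = 0.808 with an estimated correlation), and that median was 0.01 with quantile scaling. G1/S genes (adjusted p = 7.97e-05, estimated 0.313), stroma genes (0.00507, estimated 0.314), myoid genes (0.0156, estimated 0.614), X escape genes (0.0188, estimated 0.231) and DNA methylation genes (0.0268, estimated 0.239) moved as in the full set. So did polycomb genes (0.0352, estimated 0.56), feeder genes (0.0352, estimated 0.718), glycolysis genes (0.0404, estimated 0.56) and trophoblast genes (0.0428, estimated 0.313 and 0.187 with the block). Visceral endoderm genes rose in 1 of 9, and 2 adjusted over the list alone (adjusted p = 0.0428, estimated 0.718). The EB samples differed here: the list averaged 2.84 in MR2-1 EB and 0.73 in RM1-1 EB, against 0.49 to 0.88 in AdESC samples. G2/M genes passed with the block alone (adjusted p = 0.0284, against 0.0863). For the Wnt target, interferon, lung epithelial, endothelial and Leydig lists, none of them called, median and mean differed in sign.

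Cells from the somatic part of the testis of chimaeras (RM1-1 and RM2-1, n = 2) were set against the same AdESC samples to ask what AdESC-derived cells express in a tissue. Cav1 (chromosome 6), the main coat protein of caveolae, rose from 0.0279 ± 0.0558 to 126 ± 7.74 FPKM (6.96 ± 0.54, adjusted p = 0.00024). The hyaluronan receptor Cd44 rose from 0.0107 ± 0.0152 to 104 ± 37.1 FPKM (6.65 ± 0.57, adjusted p = 0.00039). Vim (8.48 ± 0.90), the chemokine Ccl2 (7.46 ± 1.56), Tagln (8.51 ± 1.41), Ndn (4.66 ± 4.50 to 165 ± 87.1 FPKM, 5.11 ± 0.90) and Cd81 (1.92 ± 0.24) rose as well. Nanog (-8.85 ± 0.44), Tdh (-8.38 ± 1.15), Mylpf (-7.81 ± 0.40), Dnmt3l (-7.73 ± 1.26) and Tfcp2l1 (-6.82 ± 0.46) fell, and Pou5f1 was listed at 0 in both testis samples against 77.9 ± 10.1 FPKM in AdESCs. Sox2 (8.17 ± 11.6 FPKM, adjusted p = 0.0754) and H19 (adjusted p = 0.962) did not pass.

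The testis fit called 486 genes up and 452 down, 938 of 8421, with 149 listed at 0 in a group, and 182 with the line as a block (89 up, 93 down). Without an AdESC sample the count was 517 (MR1-1), 525 (MR2-1), 547 (RM1-1) and 573 (RM2-1), and the simulated recovery was 0 of 100 at a log2 of 1 and 8 of 100 at 2. The samples were unlike each other: neuron and glial genes averaged 2.31 on the log2(FPKM + 1) scale in RM1-1 testis and 0.8 in RM2-1 testis, and the myoid list 1.48 and 6.54.

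Naive genes fell in 13 of 19, and 16 adjusted over the list alone (median -4.33, adjusted p = 2.19e-13). Germ cell genes fell in 7 of 9, and 8 adjusted over the list alone (median -3.3, adjusted p = 7.53e-07). Both were lost with an estimated correlation (adjusted p = 0.0591). Fibroblast genes rose in 8 of 27, and 13 adjusted over the list alone (median 2.61, adjusted p = 5.42e-08, and adjusted p = 0.447 with an estimated correlation). Feeder genes rose in 2 of 10, and 3 adjusted over the list alone (adjusted p = 0.00171, estimated 0.604). Myoid genes rose in 2 of 9, and 3 adjusted over the list alone (median 3.52, adjusted p = 0.00897, estimated 0.604), with Myl9 (6.29 ± 1.15). DNA methylation genes fell in 5 of 10, and 6 adjusted over the list alone (adjusted p = 0.00112, estimated 0.142), with Dnmt3b (-3.83 ± 0.57). Lung epithelial genes fell in 3 of 5, over all genes and adjusted over the list alone (median -4.3, adjusted p = 0.0208, estimated 0.334), which were the epithelial genes Epcam and Cdh1, listed at 0 in testis, and Krt19 (-4.69 ± 0.71). X-linked genes gave 13 up and 32 down of 203 (23 and 54 adjusted over the list alone, adjusted p = 0.0015, estimated 0.218). G1/S genes (adjusted p = 8.13e-05, estimated 0.334), G2/M genes (0.000513, estimated 0.604), stroma genes (0.00112, estimated 0.334) and glycolysis genes (0.0015, estimated 0.334) moved as in the full set. So did ribosomal protein genes (0.0195, estimated 0.831), polycomb genes (0.0223, estimated 0.45) and trophoblast genes (0.0402, estimated 0.334 and 0.126 with the block). The Sertoli (adjusted p = 0.219) and Leydig lists (0.385) were not called, with 1 member up in each. The neuron list had 3 up and 1 down of 13 (adjusted p = 0.0979), and the glial list passed with the block alone (adjusted p = 0.0413, against 0.0959). For the mesoderm and endoderm, Wnt target, interferon and leukocyte lists, none of them called, median, mean and test differed in sign.

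Tested against each other, testis and EB samples differed in 6 genes. Tm4sf1, a tetraspanin-like protein of endothelium and mesenchyme (6.59 ± 0.56, adjusted p = 0.00775), and the receptor kinase Axl (4.91 ± 0.59, adjusted p = 0.0328) were higher in testis. Tnnc1 (-5.33 ± 0.66, adjusted p = 0.0328), Lin28a (-5.24 ± 0.52, adjusted p = 0.00876), the let-7 target Trim71 (-4.86 ± 0.47, adjusted p = 0.00876) and the aminotransferase Aadat (-3.86 ± 0.49, adjusted p = 0.0328) were lower. Of the 13 neuron genes 12 had a positive difference, but 0 passed by limma over all genes and 2 adjusted over the list alone (median 1.72, adjusted p = 0.000594, estimated 0.397). The neuron list averaged 1.91 in RM1-1 testis, 0.76 in RM2-1 testis and 0.61 in both EB samples. Mesoderm and endoderm genes (median -2.26, adjusted p = 0.000594, estimated 0.233), visceral endoderm genes (-1.67, 0.000833, estimated 0.691) and lung epithelial genes (-2.04, 0.00125, estimated 0.233) were lower. So were G2/M genes (-0.62, 0.0037, estimated 0.844), cardiac genes (-2.22, 0.0116, estimated 0.233) and DNA methylation genes (-0.41, 0.0138, estimated 0.233 and 0.0785 with the block). Fibroblast genes were higher (0.22, adjusted p = 0.0411, estimated 0.844 and 0.438 with the block).

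Whether X-linked transcripts as a set change when AdESCs differentiate was tested with 186 X-linked genes at 5 FPKM or more, each cell giving the median log2 ratio of its genes to their mean over the 11 samples. The sample value, the median over cells, was 0.18 ± 0.07 in AdESC samples (n = 4) and -0.99 ± 0.34 in differentiated ones (n = 7). The difference was -1.17 (p = 0.00606 by a two-sided exact permutation test over 330 splits, the smallest it can give). This test, like the permutation tests below, treats the 11 samples as independent although they come from 4 lines. No version that shuffles within lines was run. The size of the difference depended on the minimum level: with genes at 1 FPKM or more it was -0.74, and at 20 FPKM or more -0.98. RM1-1 testis (-0.55) and neuron (-0.61) lay highest among the differentiated samples and MR1-1 fibroblast (-1.47) lowest, and the AdESC samples ran from 0.1 to 0.28. For 5251 autosomal genes measured alike the difference was -0.33 (-0.25 ± 0.16 to -0.58 ± 0.38, p = 0.109, exact permutation). X-linked minus autosomal, a measure chosen after seeing the data, differed by -0.84 (0.44 ± 0.13 to -0.41 ± 0.12, p = 0.00606, exact permutation). Planted changes of -1 and -2 in simulated data came back as -0.93 and -1.83.

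Single X-linked genes show how uneven the change was. Hprt stood at 1 FPKM or more in 24 of 24 AdESC cells and in 0 of 63 differentiated ones, Bex4 in 24 and 0, and Rlim in 20 and 0. Timm17b stood so in 24 and 1, Armcx1 in 15 and 1, and Fam122b in 11 and 0. All 6 were listed at 0 in both rat ESC lines. Vamp7, which both mouse lines listed at 0, stood at 1 FPKM or more in 16 AdESC cells and in 34 differentiated ones. As a background, Nanog reached 1 FPKM in 24 and 0 cells, Pou5f1 in 24 and 3, Sox2 in 24 and 12, and H19 in 3 and 19. Capture of transcripts in single cells is incomplete, and no depth is known, so a value below 1 FPKM does not show that a gene was silent.

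**Figure D4:**
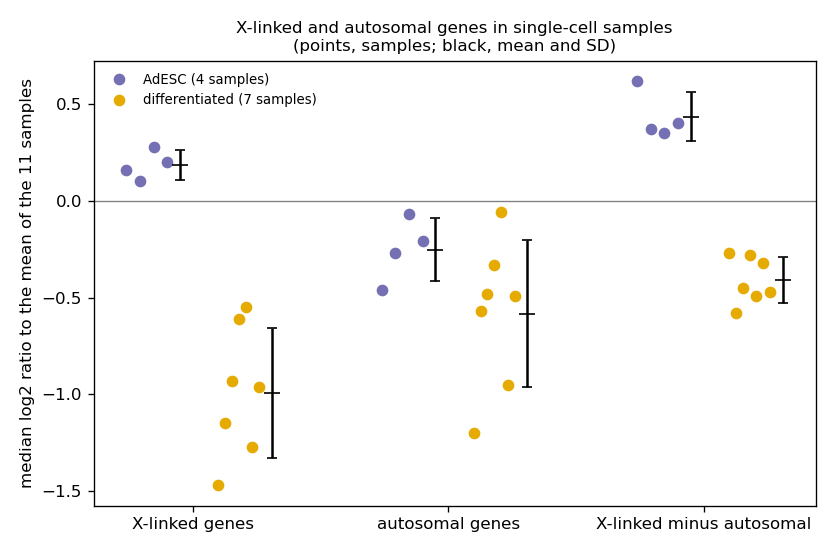
Median log2 ratio of X-linked and of autosomal genes to their mean over the 11 samples, 1 point per single-cell sample, with AdESC and differentiated samples apart. X-linked values averaged 0.18 in AdESC samples and -0.99 in differentiated ones, and autosomal values -0.25 and -0.58.

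Fibroblasts (MR1-1), neurons (RM1-1) and lung cells (RM2-1) came as 1 sample each. They are given against the AdESC sample of the same line without a test. In the neuron sample (8 cells) the neuron list was positive in 22 of 24 genes with a median log2 ratio of 2.70, the glial list reached 4.83 and cholesterol synthesis 1.53, each above all of 10000 random lists. Fabp7, a lipid carrier of radial glia, stood at 1389 FPKM, the metallothionein Mt3 at 852, the growth factor Ptn at 390.8 and the growth-cone protein Gap43 at 224.4, while the naive list lay at -4.46. In the fibroblast sample (10 cells) the fibroblast list was positive in 21 of 23 genes (median 3.47). The visceral endoderm (2.97) and Sertoli lists (3.40) were high too. Large rises were Srgn (323.9 FPKM, at 1 FPKM or more in 8 cells) and the proteoglycan Lum (146.4, in 4). Others were the water channel Aqp8 (145.4, in 5) and the epidermal keratin Krt14 (118.2, in 3). Col1a1 reached 1 FPKM in 5 cells, Dcn in 3 and Fstl1 in 9, and the epithelial Epcam in 8 and Cdh1 in 7.

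In the lung sample (4 cells) only 4 of the 17 measured genes of the lung epithelial list passed the level filter, 1 of them positive and 3 lower (median -5.30). The general epithelial genes Epcam and Cdh1 were at 110.3 and 15.58 FPKM in RM2-1 AdESC cells and listed at 0 in lung. So this median says little of lung epithelium. Sftpc, the surfactant protein of alveolar type II cells, was listed at 0. The myoid list stood at 6.54, the feeder list at 5.38, the fibroblast list at 4.57 (21 of 22 genes positive), the Leydig list at 3.56 and the Sertoli list at 2.97. Ccl2 reached 3999 FPKM, Tagln 2390, Cyp11a1, which starts steroid synthesis, 1028 in the mean with 2 of 4 cells at 1 FPKM or more, and the steroidogenic Star 102.4.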

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

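The search for outlying values followed a rule fixed beforehand, and the test of testis against EB samples was chosen after the results were seen. Of 124 groups of 4 to 10 values, 7 held a value far from the others, and chance gives about 1 in 20 groups, so the number found is at the level of chance and none was weighed further. Values are means of log2(FPKM + 1) over a list, and no biological explanation was tested.

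Among the 4 bulk AdESC lines, MR1-1 was low in leukocyte genes (0.79, the other lines 1.17 to 1.24) and MR2-1 high in erythroid genes (1.11, the other lines 0.28 to 0.32). In the single-cell AdESC samples RM1-1 was high in G2/M genes (6.31, the others 5.88 to 5.91). Among the 7 differentiated samples MR2-1 EB was high in endothelial genes (1.45, the others 0.1 to 0.51) and in erythroid genes (0.82, the others 0 to 0.19), and RM2-1 lung in Leydig genes (3.78, the others 0.64 to 1.23). In RM1-1 EB a single cell held 5619 genes at 1 FPKM or more, the other cells 4961 to 5108.

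Testis and EB samples, each set against AdESC cells, moved differently in 6 genes by a test of the difference itself, 2 higher and 4 lower in testis. The testis group joins samples that differ from each other in neural and myoid genes.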

How the results depend on the processing

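The alternatives were chosen before the data were examined, except the fits without genes listed at 0 in a species, the fits without RM1-1 testis, RM2-1 lung and MR1-1 fibroblast, the X-linked measure minus the autosomal one, and the list tests against mouse without each library, which were chosen after seeing the data. Of the gene counts under an alternative 93 stayed within 1.5 times the count reported and 33 did not, and all 24 counts of inheritance classes did. All 17 values of the X-linked test kept their direction and stayed past the threshold, the smallest being -0.74. Of the named genes 4538 values kept direction and side of the threshold, 768 fell short of it and 4 reversed. The count against the parental mean was the least stable: 240 with a pseudocount of 0.1, 2 with the parental mean on linear FPKM, 41 without genes listed at 0 in a species (all 41 among the 112) and 0 by limma (280 at an unadjusted p under 0.05) with the 4 parental lines as 1 group, whose own spread then holds the species difference. On linear FPKM Fbxo15 (-0.411), Rpl7a (-0.158), Rps9 (-0.222) and Rps19 (-0.456) reversed, since a log2 mean is pulled down by a parent at or near 0. With RM and MR as separate groups 156 genes differed from mouse, and the cause was not tested. With the number in the line name as a block RM and MR differed in 21 genes (11 up, 10 down); log2 values of lines of the same number correlated across genes at 0.964 to 0.966 and of other numbers at 0.896 to 0.939. A fit chosen after seeing the data, of AdESC lines numbered 2 against those numbered 1 with RM and MR as a block, gave 403 genes higher and 488 lower of 8794. What the numbers stand for is not known. With the line as a block EB cells differed in 25 genes and testis cells in 182, cause not tested. Leaving out each line or sample in turn gave 151 to 344 genes against mouse, 223 to 1063 against rat, 1059 to 2435 between species, 56 to 137 against the parental mean, 0 to 0 between RM and MR, 791 to 1367 for differentiated cells, 222 to 676 for EB cells and 517 to 1133 for testis cells. Where this left a group with a lone sample, that sample was assumed to vary like the other groups. In the X-linked test leaving out a sample gave differences of -1.29 to -1.1, the mean over cells -1.16, and leaving out the 3 samples named above -1.18. Leaving out each library gave 7 (without F145) to 13 lists against mouse, where 12 were called with all, and the adjusted p of the fibroblast list ran from 8.82e-20 (without F146) to 0.99 (without F145), where camera also turned its direction to up. List tests of the other comparisons were not repeated in this way. With an estimated correlation camera called 0 lists against mouse (12 with the preset one), 0 against rat (5), 0 between species (8), 0 against the parental mean (8), 0 between RM and MR (18), 2 for differentiated cells (15), 0 for EB (16), 0 for testis (15) and 0 for testis against EB (8). Leaving out cells with fewer than 2000 genes removed none, since the lowest cell held 3444. The alternatives for mouse and rat alleles and the stricter allele fraction were not run. Depth is unknown, and it limits the genes near 0 most.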

Other observations

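Of the tests in this part only the rank correlation across X-linked genes was chosen before its result was seen, and the others were chosen after. Imprinted genes stood at unlike levels in the single-cell samples. H19 stood at 92.7 FPKM in MR1-1 fibroblasts and 104.8 in RM1-1 EB, at 2.65 in MR2-1 EB and at 1.98 or less in the neuron, lung and testis samples, against 0.019 to 4.01 in the AdESC samples. Igf2, its paternally expressed neighbour, was 28.3 FPKM in RM1-1 EB and 6.69 in fibroblasts, and 0.99 or less in every other sample. Ndn reached 226 FPKM in RM1-1 testis, 128 in the neuron sample and 103 in RM2-1 testis, and Nnat 117, 53.6 and 42.6 in the neuron sample, RM1-1 EB and RM1-1 testis. Cdkn1c, a maternally expressed cell-cycle inhibitor, was highest in RM1-1 EB (12.6) and fibroblasts (6.97), and listed at 0 in RM1-1 testis and in MR1-1 AdESC. No test was run on these values, which rest on 1 sample each.

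Some samples held genes that their labels do not name. The visceral endoderm list averaged 2.67 on the log2(FPKM + 1) scale in MR1-1 fibroblasts and 2.84 in MR2-1 EB, and 0.73 or less in the other differentiated samples, with Gata4 at 27.4 and 60.7 FPKM and Lama1 at 64.2 and 214.8 FPKM. Gata4, which somatic testis cells also express, stood at 25.9 FPKM in RM2-1 lung. Steroidogenic genes were highest in RM2-1 lung, with Cyp11a1 at 1028 FPKM and Star at 102.4, against a Star of 18.1 in RM2-1 testis. Clu, a secreted chaperone abundant in Sertoli cells and other epithelia, stood at 2617 FPKM in RM2-1 lung and 1330 in MR2-1 EB. Across genes, which are not independent replicates, the mean profile of RM2-1 lung was closest to RM2-1 testis (rho = 0.89) and that of MR1-1 fibroblasts to MR2-1 EB (rho = 0.88). Cells of the 2-cell-like state were read from a single measured gene, at 5.38 to 6.66 in bulk and 6.19 to 7.39 in cells, which says nothing of such a state.

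The X-linked genes Armcx1, Bex4, Fam122b, Hprt, Rlim and Timm17b, all listed at 0 in both rat lines, had a median log2 ratio of -4.23 between differentiated and AdESC cells. Cells that carry rat transcripts alone are argued against by the 62 autosomal genes listed at 0 in rat, with sample medians of -1.02 to -0.36. Lower detection in differentiated cells is argued against by random autosomal lists matched on level, of which 0% of 10000 fell as low (lowest -2.77), and a fall of all genes listed at 0 in rat by lists drawn from 68 of them, of which 0.02% did. A mouse X chromosome that is not transcribed in differentiated cells may explain the pattern, but across 166 X-linked genes the ratio to AdESC cells followed the rat share of parental FPKM with rho = 0.07, against -0.04 for 4675 autosomal genes (percentile 89.13), so it cannot be told apart from its absence because AdESC values do not part the genomes.

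The RM1-1 sample named testis held neuron and glial genes at a mean log2 of 2.31 over 46 genes, its own EB sample 0.89 and its neuron sample 3.26. A swap with the neuron sample is argued against because the neuron sample stood 0.95 higher in these genes. A property of line RM1-1 is argued against because its EB sample stood lower, with a difference of -1.42. Other cells under the testis name of RM1-1 cannot be told apart from a biological difference of testis tissue between chimaeras, which was not tested: 4 of 4 cells ranked the neuron sample closest among the other sample means (rho 0.748 to 0.822 across genes), but this repeats the likeness of the sample cell by cell and both would give it.

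Feeder fibroblast genes averaged 6.61 on the log2(FPKM + 1) scale in F145, 3.69 in F146, 1.78 to 3.60 in the AdESC lines and 0.11 or less in the rat lines, so only F145 stood well above AdESCs. A different scaling of mouse and rat values is argued against because it would move all genes alike: the median log2 difference, rat minus mouse, was 0.09 over the other 8784 genes tested and -5.1 over the 10 feeder genes, and 0% of 10000 random lists matched on mouse level lay as low (lowest -1.95). Fibroblast genes made by AdESCs are argued against, as 0 of 24 single AdESC cells held Col1a1, Col1a2 or Col3a1 at 10 FPKM or more. At 1 FPKM or more 3 held Col1a1. No single mouse ESC was measured. Fibroblast RNA in bulk cultures is a candidate, as 10 of 10 feeder genes had a single-cell AdESC mean under 0.1 of bulk. Col1a1 was 0.42 FPKM in AdESC cells and 54.49 in bulk RM1-1. Feeder fibroblasts, on which stem cells are often grown, were not measured here, and a choice of G0/G1 cells would not by itself remove them.

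Other splits of the samples were tried for both large fits. For the parental mean 4 of 100 drawn splits, of 210 possible, gave as many genes as the real one (112, the highest other 949), a share at which chance can be excluded only if all splits were alike. They were not: splits that put mouse with rat lines in a group widen its spread. The count was also 0 by limma (280 genes at an unadjusted p under 0.05) with the parents as 1 group of 4 lines and 2 on linear FPKM, so chance is left open for it. The split with 949 set F145, F146, MR2-1 and RM2-1 against DA25 with DA53 and MR1-1 with RM1-1, and its count, several times the real one, points to a structure of the samples. It parts mouse from rat lines and the line numbers at once, so its size cannot be put down to either. For differentiated against AdESC cells only the real split, 1 of 100 drawn from 330, gave as many as 1343 genes, and the highest other gave 32, so chance can be excluded.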
